A study of Mus musculus with 7 samples.

How the data were processed

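RNA was sequenced from Pdgfra-low CD81+ cells sorted from the intestinal mesenchyme of mice. Per the labels, RNA was extracted with a column kit for small samples, mRNA was captured on poly-T beads, cDNA was primed with random hexamers, and libraries were sequenced on an Illumina platform. The 7 libraries are 3 wildtype controls, 2 libraries from mice 4 days after Apc was inactivated in epithelial cells, and 2 libraries from 6 days after. Inactivation used floxed Apc alleles and the Villin-CreERT2 driver.

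The deposited values are FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, made by the authors, in a table with 1 column per library. How the mapped fragments were counted is not stated. The submitters' processing notes name kallisto 0.46.1 and DESeq2 1.40.1 and the mm9 build without saying what each was used for, so the step that produced the FPKM values is not known. The table holds 25493 entries under upper-case gene symbols without gene identifiers, and 293 symbols occur more than once. For these the entry with the highest mean was kept, which left 24908 symbols, of which 24411 matched mouse gene symbols of the reference annotation and are printed in that spelling. No positions are given, because the reference annotation is on another genome build.

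Columns were assigned to groups by their names. The names place 1 control and both day 4 knockout libraries in a day 4 harvest set, and 2 controls and 1 knockout library in a day 6 set. The remaining knockout column carries no day, and was taken as the second day 6 knockout library because no other sample was left for it. Its place in the day 6 set, used wherever controls of the same set are used, was assumed, and the sets themselves rest on the column names alone. The control columns cannot be tied to the numbered control titles, so controls are named here by their set. Nothing in the labels says whether the libraries came from separate animals, so the p-values measure only the spread between these samples.

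The table holds no read counts, so the sequencing depth of the libraries is unknown and no counting interval or detection floor can be given. Relative depth within a set was estimated from the most frequent ratio between 2 libraries of FPKM values below 0.2, taken gene by gene on a log2 grid of 0.02. Against the day 4 set control, the relative depth was 0.747 for day 4 knockout replicate 1 and 0.824 for replicate 2. Against the first day 6 set control, it was 0.883 for the second control and 1.6 for each day 6 knockout library. Few genes held the most frequent ratio, so these depths are rough. In the day 4 set it was held by 147 of 2017 and 79 of 2003 genes, in the order given. For the day 6 set it was held by 29 of 911, 42 of 1280 and 48 of 1261. The columns summed to between 351323 and 427369 FPKM, and between 10914 and 11342 genes per library reached 1 FPKM.

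Genes with at least 1 FPKM in at least 2 of the 7 libraries were tested, whatever their group, which left 11735 genes. Values were analysed as log2(FPKM + 1), so the log2 changes printed understate the change of genes near 1 FPKM. limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all 7 libraries with 4 residual degrees of freedom. The empirical Bayes prior followed mean intensity and had 3.78 degrees of freedom. The contrasts were day 4 against wildtype, day 6 against wildtype, the average of both days against wildtype, and day 6 against day 4. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Standard errors (SE) of log2 changes come from this model, and standard deviations (SD) are between libraries on the FPKM scale. The same 3 controls stand in both comparisons with wildtype, so the log2 changes of the 2 days share their error.

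Fixed gene lists for mesenchymal subtypes, signalling pathways, matrix, inflammation, metabolism, other cell types, handling and sex were tested. There were 47 lists, and 41 of them had at least 5 tested members. Each was tested with camera from limma at a preset correlation between genes of 0.01, and p-values were adjusted over the 41 lists within each contrast. Camera was repeated with a correlation estimated from the data, and fry was run as a second set test. Counts of members adjusted over the list alone are given beside those adjusted over all genes.

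The comparisons, the filter, the threshold, the lists and the rule for naming genes were chosen before the data were examined. The rule always names Apc, Pdgfra, Cd81, Grem1, Rspo3 and Wnt2b. In each comparison with wildtype it names up to 12 genes with the largest positive and up to 12 with the largest negative log2 change among genes past the threshold, provided that all knockout libraries lay beyond all 3 controls and the mean over the 7 libraries was at least 3 FPKM. For day 6 against day 4 it names up to 5 in each direction. Where fewer than 5 passed, the genes with the smallest p filled up to 5 and are said to have missed the threshold. Up to 4 members with the smallest p are named for a list that is described. Predicted genes, receptor and immunoglobulin segments and mitochondrially encoded genes were left out. Genes are named in rank order, and a few results past the threshold are not reported here.

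The test was checked on simulated data with 11735 genes, of which 200 were changed. The changed genes were drawn only from the more highly expressed genes, with independent noise and no harvest set. Recovery among genes with lower values was not simulated. In the simulated day 4 comparison 53.7% of genes changed 2-fold and 100% of those changed 4-fold were recovered, with 10 false calls among 178. In the simulated day 6 comparison these shares were 62.7% and 95.5%, with 15 false calls among 187. The share of false calls was above the threshold of 0.05 in both. In the simulated average of both days these shares were 79.1% and 98.5%, with 9 false calls among 193, and day 6 against day 4 gave 7 false calls among 173. Unchanged groups were simulated 100 times with normal noise at each gene's moderated SD, for the correlation of the changes at the 2 days and for the number of genes with the same sign.

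Alternatives fixed in advance covered the pseudocount, the filter on low values, the scaling between libraries (to an equal total, quantile normalization and trimmed mean of M values), the samples in the fit, the empirical Bayes prior, the threshold, a replicate block, the set test and leaving out each library. Alternatives added after seeing the data were controls of the same harvest set, harvest set as a term, Ddx3y level as a covariate, and setting implausible zeros missing. The zeros concern 7 genes listed at 0 in at least 1 library although their median was at least 10 FPKM, and no group mean is printed for them. The planned use of DESeq2 as a second test was not run, because it needs read counts. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.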

Results

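Gene expression was measured by poly-A RNA sequencing in Pdgfra-low CD81+ mesenchymal cells of the mouse intestine. This population, also called trophocytes, lies beneath the crypts and supplies Grem1, R-spondins and WNT ligands to the epithelial stem cells. The cells came from 3 wildtype controls and from mice in which Apc, the scaffold that keeps beta-catenin low, had been deleted in the epithelium only. Knockout libraries were made 4 days (n = 2) and 6 days (n = 2) after inactivation. The comparisons ask how these stromal cells change while the neighbouring epithelium is driven by WNT signalling.

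Control cells expressed the sort markers Cd81 and Pdgfra and the trophocyte genes Grem1, Rspo3 and Wnt2b. No other cell population was sequenced, so enrichment cannot be judged. Cd81 stood at 134 ± 21.0 FPKM (SD, n = 3) in controls, Pdgfra at 58.5 ± 3.69 FPKM, Grem1 at 179 ± 15.5 FPKM, Rspo3 at 25.1 ± 0.915 FPKM and Wnt2b at 29.1 ± 8.14 FPKM. Apc itself ranged from 2.22 to 3.29 FPKM over the 7 libraries, and since the allele was deleted in epithelial cells it does not check the knockout here.

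Libraries differed in ways the genotype does not set. On the first principal component, which held 34.8% of the variance, the day 6 set controls lay at -24.6 and -31.7, the day 4 set control at 6.83, the day 6 knockouts at -7.55 and -11.4 and the day 4 knockouts at 29.0 and 39.4. Gapdh was 193 to 277 FPKM in the day 4 set and 66.5 to 91.4 FPKM in the day 6 set, knockout and control alike. Day 4 knockout replicate 2 had the lowest Cd81 (32.4 FPKM), the lowest Ptprc (0.532 FPKM, against 2.86 to 8.47 FPKM in the others) and the highest mean of telocyte markers (4.41 on the log2 scale, against 3.39 to 3.74). Day 4 knockout replicate 1 had the highest Epcam (5.70 FPKM) and the highest mean of B and plasma cell markers (5.28). Day 6 knockout replicate 1 had the lowest mean of interferon-stimulated genes (2.63, against 3.23 to 4.17) and the highest mean of epithelial markers (2.62, against 1.18 to 1.93). Ddx3y, a Y-linked gene, was 39.9 FPKM in the first day 6 set control, 34.8 FPKM in day 6 knockout replicate 1 and 9.10 FPKM in day 6 knockout replicate 2, and at most 0.182 FPKM in the other 4.

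**Figure D1:**
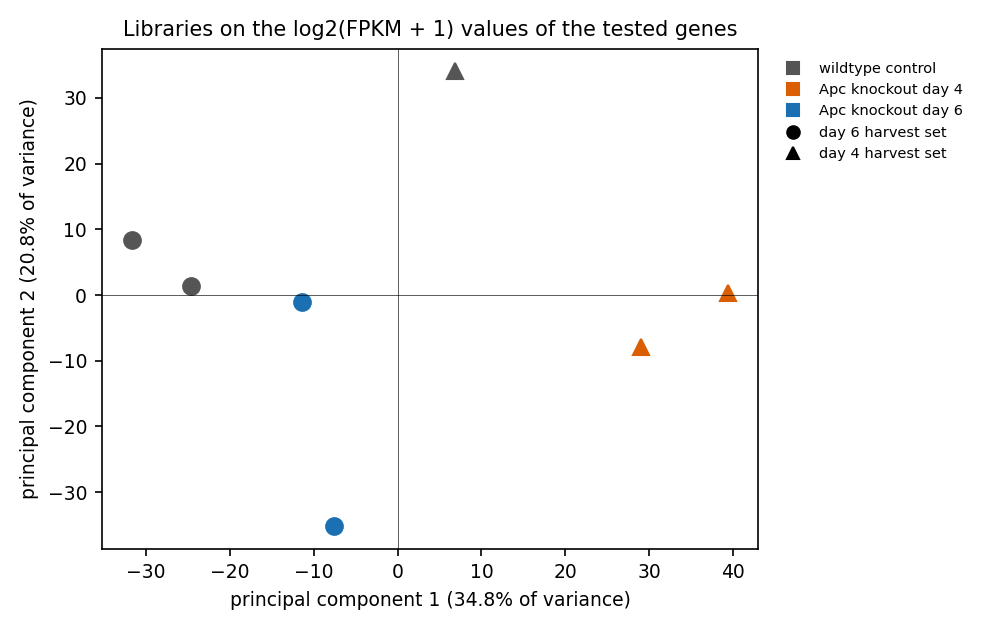
Principal components of the 7 libraries from log2(FPKM + 1) of the tested genes, with the first component (34.8% of the variance) on the horizontal axis and the second (20.8%) on the vertical axis. Colours give the group and marker shapes the harvest set. The day 4 knockout libraries, at 29.0 and 39.4, lie farthest to the right, and the day 4 set control, at 6.83, lies between them and the day 6 set controls.

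Averaged over both days, Serpina3m, Pla1a and Alpl led a small set of genes that were higher in cells from mice with Apc-deficient epithelium. Serpina3m, a serine protease inhibitor of the antichymotrypsin family, was 1.84 ± 0.967 FPKM (SD, n = 3) in controls, 54.5 ± 27.9 FPKM (n = 2) at day 4 and 31.1 ± 0.438 FPKM (n = 2) at day 6. Pla1a, a phosphatidylserine-specific phospholipase, was 0.944 ± 0.197 FPKM in controls, 22.9 ± 14.3 FPKM at day 4 and 13.5 ± 0.0788 FPKM at day 6. Alpl, tissue-nonspecific alkaline phosphatase, was 26.8 ± 5.53 FPKM in controls, 330 ± 47.2 FPKM at day 4 and 118 ± 24.9 FPKM at day 6. In all, 19 genes rose and 0 fell by limma, where 1625 genes had an unadjusted p under 0.05 and 587 were expected by chance.

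The log2 change with both days averaged was 3.90 ± 0.31 (SE) for Serpina3m (adjusted p = 0.00663), 3.19 ± 0.29 for Pla1a (adjusted p = 0.0109) and 2.84 ± 0.19 for Alpl (adjusted p = 0.00512). Next in rank came Ttyh1 at 2.75 ± 0.22, the cytokine Il11 at 2.72 ± 0.34, the lipocalin Apod at 2.49 ± 0.18, the kinase Map3k6 at 2.47 ± 0.26 and Cpne7 at 2.41 ± 0.26. Serpina3n, a close paralog of Serpina3m and the most abundant of these 12 genes, changed by 2.28 ± 0.22, from 252 ± 27.4 FPKM in controls to 1511 ± 271 FPKM at day 4 and 1029 ± 318 FPKM at day 6. Cyp1b1, a retinoid and steroid metabolising cytochrome, changed by 2.14 ± 0.24, the B cell attracting chemokine Cxcl13 by 2.12 ± 0.24 and the small heat shock protein Hspb7 by 2.01 ± 0.20. All 4 knockout libraries lay above all 3 controls for each of these 12 genes. In the other direction no gene passed. The genes with the smallest p there were the guidance molecule Sema3c at -0.94 ± 0.13 (adjusted p = 0.0532), the chaperone Cryab at -0.90 ± 0.13 (adjusted p = 0.0532) and Angptl1 at -1.50 ± 0.21 (adjusted p = 0.0532).

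**Figure D2:**
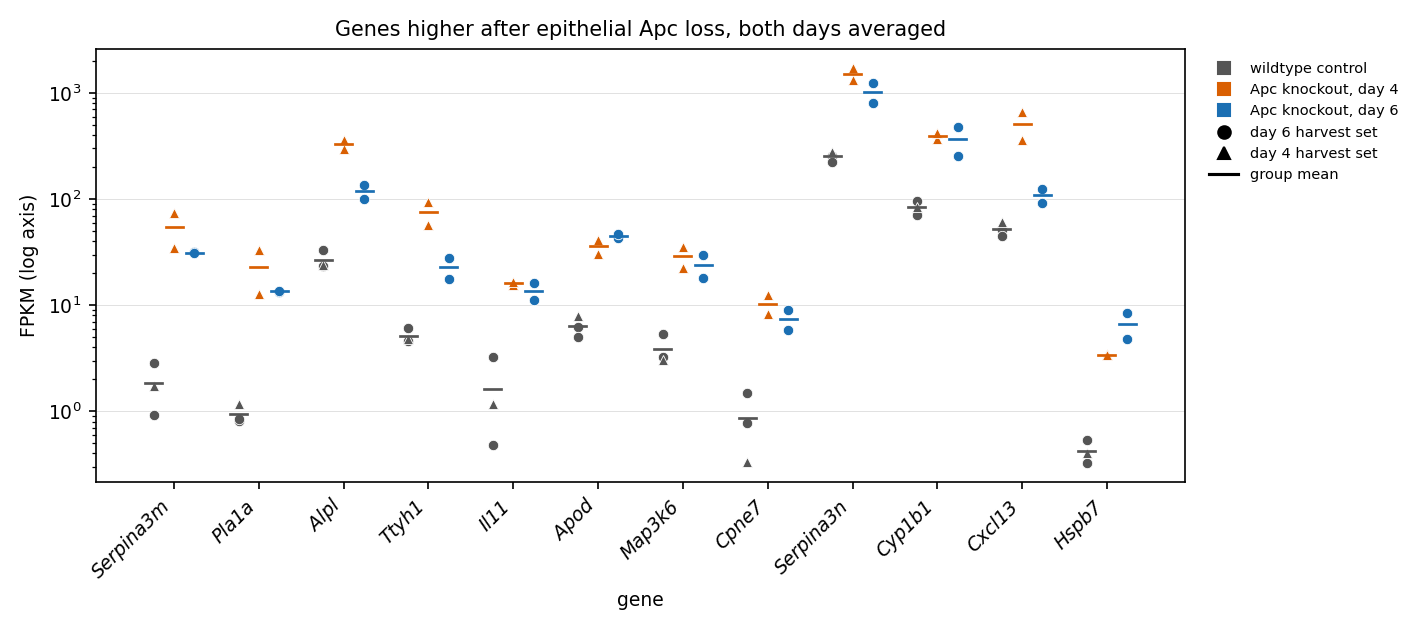
FPKM on a log axis for the 12 named genes higher with both days averaged, 1 point per library, with colours for the groups, circles for the day 6 harvest set, triangles for the day 4 set and lines at the group means. Serpina3m ranges from 0.926 to 2.85 FPKM in the controls and from 30.8 to 74.3 FPKM in the 4 knockout libraries.

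Against the controls of their own harvest set, the median log2 change of the 19 genes was 2.30 at day 4 and 2.06 at day 6. With these within-set differences averaged in place of the pooled controls, the median log2 change of the 19 genes was 2.13, against 2.14 before. The 19 genes had been selected for a small spread among these same controls. The count of 19 became 5 without the second day 6 set control, 8 without the first and 77 without the day 4 set control. It became 8 without day 6 knockout replicate 1, 53 without replicate 2, 45 without day 4 knockout replicate 1 and 11 without replicate 2. With no filter on low values 0 genes passed. Over all tested genes the 4 knockout libraries lay above all controls for 624 genes and below for 772, where chance gives 335 each (2.86%).

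Among the lists, the EGF family ligands, which drive epithelial growth through the EGF receptor, were higher with both days averaged (median log2 change 1.20, 5 of 6 tested members positive, camera adjusted p = 0.000296). The call did not hold with an estimated correlation between genes (adjusted p = 0.590 with an estimated correlation) or by fry (adjusted p = 0.0605). None of the 6 passed over all genes and 4 were higher adjusted over the list alone: Areg at 1.51 ± 0.21, Ereg at 1.43 ± 0.27, Epgn at 1.19 ± 0.27 and Nrg1 at 1.21 ± 0.44. Blood endothelial markers were also higher as a list (12 tested, median 0.33, camera adjusted p = 0.0395), with 0 members past the threshold over all genes or over the list alone. This call was lost with quantile normalization (adjusted p = 0.0995), with controls of the same harvest set (adjusted p = 0.0856) and with an estimated correlation (adjusted p = 0.976 with an estimated correlation). It was also lost without the first (adjusted p = 0.0534) or the second (0.230) day 6 set control, without day 6 knockout replicate 2 (0.0993), and by fry (0.778). The inflammatory fibroblast cytokines and chemokines did not move as a list (camera adjusted p = 0.849), and 2 of 28 tested members rose: Cxcl13 and Il11. Of 11 tested lipid and adipogenic genes Apod rose, and 5 were higher and 1 lower adjusted over the list alone. The list did not pass by camera (median -0.16 and mean 0.39, adjusted p = 0.139) and passed by fry toward higher values (adjusted p = 0.0308).

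At day 4 more genes passed than with both days averaged. Of 11735 genes, 47 rose and 73 fell against wildtype, 109 of the 120 by at least 2-fold, and 2177 had an unadjusted p under 0.05 where 587 were expected. The genes that rose most were among those above. Serpina3m rose by 4.25 ± 0.37 (log2 change ± SE, adjusted p = 0.0101), Ttyh1 by 3.59 ± 0.27 (adjusted p = 0.00694), Alpl by 3.58 ± 0.23 (adjusted p = 0.00384). Pla1a rose by 3.48 ± 0.34 (adjusted p = 0.0152) and Cxcl13 by 3.21 ± 0.29 (adjusted p = 0.0103). Cxcl13 reached 510 ± 209 FPKM (SD, n = 2) from 52.2 ± 8.03 FPKM (n = 3). The collagenase Mmp8 changed by 2.99 ± 0.50, Il11 by 2.84 ± 0.40, Cpne7 by 2.62 ± 0.31, Map3k6 by 2.60 ± 0.31, Serpina3n by 2.57 ± 0.27, the G protein regulator Rgs2 by 2.40 ± 0.20 and Apod by 2.32 ± 0.21.

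Of the genes that fell at day 4, Tppp3, a tubulin-binding protein, changed most, from 366 ± 72.7 FPKM (SD, n = 3) to 56.8 ± 34.7 FPKM (n = 2), a log2 change of -2.79 ± 0.37 (SE, adjusted p = 0.0323). The fibronectin domain protein Fndc1 changed by -2.22 ± 0.33, Angptl1 by -2.13 ± 0.25, Igsf10 by -2.10 ± 0.26, Nkain4 by -2.09 ± 0.24 and the TGF-beta induced matrix protein Tgfbi by -2.05 ± 0.28. Next in rank were Wfdc1 at -1.99, Crip1 at -1.98, Col6a5 at -1.97, Glrb at -1.97 and Dmpk at -1.95.

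The trophocyte gene set did not move as a whole at day 4 (10 tested, median -0.20, camera adjusted p = 0.699), but 2 of its members fell. Cd34, a surface marker of crypt-base fibroblasts, went from 490 ± 30.6 to 195 ± 35.8 FPKM (log2 change -1.33 ± 0.21, adjusted p = 0.0413), and the canonical WNT ligand Wnt2b from 29.1 ± 8.14 to 10.9 ± 0.597 FPKM (-1.31 ± 0.23, adjusted p = 0.0489). Grem1 (-0.57 ± 0.29), Rspo3 (-0.15 ± 0.22) and the sort marker Cd81 (-1.24 ± 0.43, adjusted p = 0.189) missed the threshold, as did Pdgfra (0.78 ± 0.25, adjusted p = 0.166). In the list of WNT ligands and R-spondins 1 of 11 tested members, Wnt2b, fell, and 2 were lower adjusted over the list alone: Wnt2b and Rspo2, the latter at -1.99 ± 0.37 (adjusted p = 0.0528). Of 10 tested WNT/beta-catenin target genes none passed over all genes and 4 were lower adjusted over the list alone (Nkd1, Tnfrsf19, Ccnd1 and Dkk2; list median -0.75, camera adjusted p = 0.122). Against the day 4 set control alone this list passed toward lower values (median -0.49, adjusted p = 0.0427), as did the adventitial markers (-0.79, adjusted p = 0.0244) and Paneth cell and antimicrobial genes (-1.91, adjusted p = 1.08e-06), and the telocyte markers passed toward higher values (0.43, adjusted p = 0.0427). Single libraries carried the last 2: the mean of the Paneth genes was 2.33 in the day 4 set control but 0.501 in the first day 6 set control, near the day 4 knockouts (at most 0.652), and that of the telocyte markers was 3.39 in the day 4 set control, 3.40 in day 4 knockout replicate 1 and 4.41 in replicate 2.

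Of 6 tested EGF family ligands 3 rose at day 4. Areg went from 11.7 ± 3.36 FPKM (SD, n = 3) to 54.6 ± 0.960 FPKM (n = 2), Ereg from 192 ± 31.5 to 907 ± 353 FPKM and Epgn from 1.22 ± 0.421 to 8.56 ± 4.76 FPKM. Their log2 changes were 2.16 ± 0.25 (SE, adjusted p = 0.0274), 2.19 ± 0.32 (adjusted p = 0.0373) and 2.03 ± 0.32 (adjusted p = 0.0441). Nrg1 was at 1.76 ± 0.53 and missed the threshold over all genes (adjusted p = 0.150), and 4 of the 6 tested ligands were higher adjusted over the list alone. The list had a median of 1.89 (camera adjusted p = 6.93e-05), and the call was lost, among the alternatives run, with an estimated correlation (adjusted p = 0.474 with an estimated correlation). Against the day 4 set control alone, the median of the ligands was 2.14.

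**Figure D3:**
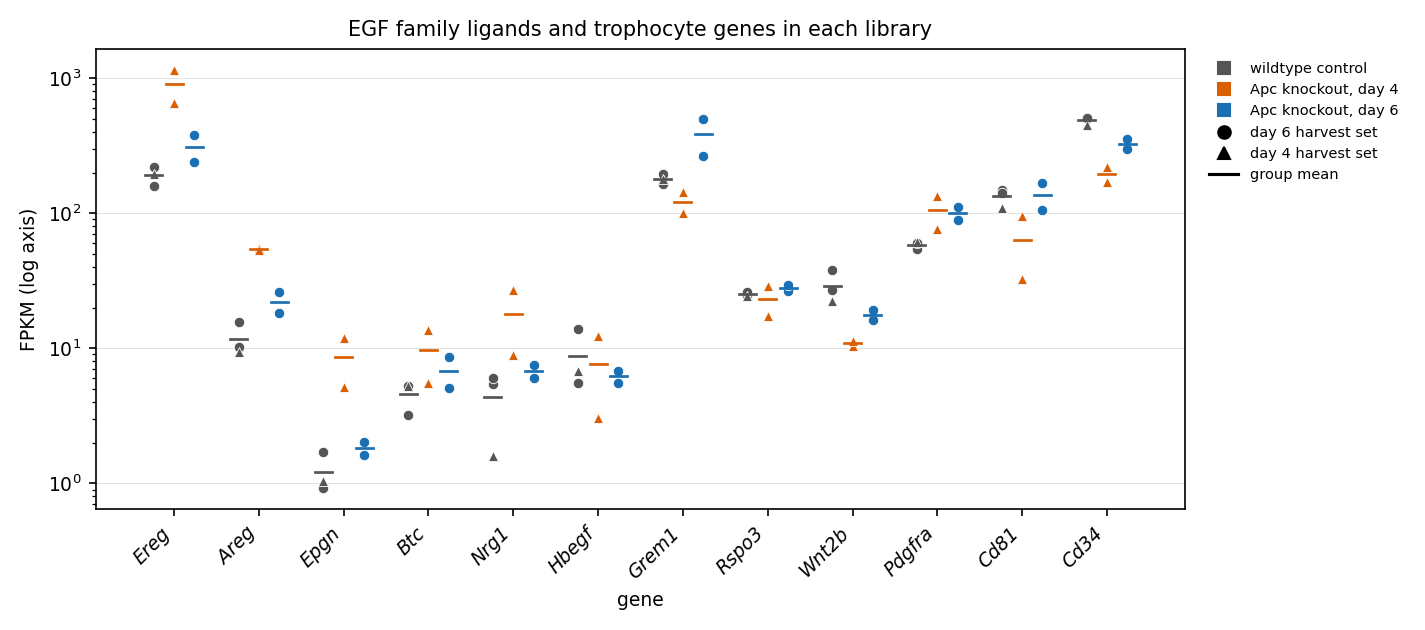
FPKM on a log axis for the EGF family ligands and for trophocyte genes, 1 point per library, with colours for the groups, circles for the day 6 harvest set, triangles for the day 4 set and lines at the group means. Areg lies between 9.35 and 15.6 FPKM in controls and at 53.9 and 55.3 FPKM at day 4, and Wnt2b between 22.4 and 38.2 FPKM in controls and at 10.5 and 11.3 FPKM at day 4.

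The list of fibrillar and fibril-associated collagens passed toward lower values at day 4 (15 tested, median -0.46, mean -0.14, camera adjusted p = 0.0267). Col5a3 passed over all genes (-1.77 ± 0.28, adjusted p = 0.0441) and 8 were lower adjusted over the list alone, among them Col5a1, Col16a1 and Col14a1. This list call was lost with an estimated correlation (adjusted p = 0.989 with an estimated correlation) and against the day 4 set control alone (median -0.44, mean 1.59, adjusted p = 0.898), in which Col1a1, Col1a2 and Col3a1 are listed at 0 and carry the mean. It was also lost without the first (adjusted p = 0.0549) or the second (adjusted p = 0.0766) day 6 set control, with the Ddx3y covariate (adjusted p = 0.106) and by fry (adjusted p = 0.485). With such zeros set missing, which took 3 of the 15 members out of the list test, the other 12 had a median of -0.75 (adjusted p = 0.00136). Col1a1 was 1976 and 2971 FPKM in the day 6 set controls, 722 and 382 FPKM in the day 4 knockouts, and 1586 and 3618 FPKM in the day 6 knockouts. In other matrix and growth factor lists 1 member each fell at day 4. These were the collagen receptor Itga11 among 13 activated fibroblast genes, Mmp23 among 17 proteases and inhibitors and Tgfbi among 14 TGF-beta genes. The others were Pdgfd among 11 FGF, HGF, IGF and related ligands, Angptl2 among 12 angiogenesis factors and Sema3c among 8 adventitial fibroblast markers.

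Lipid genes split at day 4. Of 11 tested members Apod, the fatty acid binding protein Fabp4 (1.87 ± 0.29) and the lipid droplet protein Plin2 (1.52 ± 0.26) rose, and the adipocyte lineage regulator Zfp423 fell (-1.54 ± 0.26). The list had a median of -0.20 and a mean of 0.33 (camera adjusted p = 0.178). Oxidative phosphorylation genes were slightly higher as a list (23 tested, median 0.19, camera adjusted p = 0.0267). Blood endothelial markers were higher (12 tested, median 0.59, camera adjusted p = 0.0137) with 0 members past the threshold and 4 higher adjusted over the list alone, Flt1, Egfl7, Esam and Pecam1. Both calls were lost with an estimated correlation (adjusted p = 0.989 with an estimated correlation in each), by fry (0.282 in each) and without the second day 6 set control (0.0729 in each). That of oxidative phosphorylation was also lost without the day 4 set control (adjusted p = 0.0912), and that of the endothelial markers also against the day 4 set control alone (adjusted p = 0.191). Macrophage and dendritic cell markers had a median of -0.35 (16 tested, adjusted p = 0.980), and they were far lower in day 4 knockout replicate 2 than in the other 6 libraries (mean 1.43 against 2.93 to 4.17 on the log2 scale).

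The day 4 count rested on single libraries and on the pooled controls. It was 2 without the second day 6 set control, 6 without the first, 472 without the day 4 set control, 9 without day 4 knockout replicate 2, 98 without replicate 1 (39 of them among the 120), 68 without day 6 knockout replicate 1 and 70 without replicate 2. Against the day 4 set control alone, the median log2 change of the 120 genes was 1.45 against 1.54 before, and the median SE 0.291 against 0.230. The genes had been selected for a small spread among all controls, which favours this. In that fit Col1a2, listed at 0 in this control, stood at 9.65. With no filter on low values 0 genes passed.

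At day 6 few genes passed. By limma 5 rose and 0 fell, with 852 genes at an unadjusted p under 0.05 where 587 were expected. Serpina3m changed by 3.56 ± 0.37 (log2 change ± SE, adjusted p = 0.0372), Apod by 2.66 ± 0.21 (adjusted p = 0.0144), Hspb7 by 2.38 ± 0.24 (adjusted p = 0.0372) and Alpl by 2.10 ± 0.23 (adjusted p = 0.0402). Pla1a, at 2.90 ± 0.34, missed the threshold (adjusted p = 0.0563). Of the genes with the smallest p in the other direction, the ciliary neurotrophic factor receptor Cntfr (-1.95 ± 0.40, adjusted p = 0.319) and Bola1 (-1.16 ± 0.24, adjusted p = 0.347) also missed it.

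At day 6, 4 lists passed. BMP antagonists, which protect stem cells from BMP signals, were higher (10 tested, median 0.45, camera adjusted p = 0.000300), with 0 past the threshold over all genes. Adjusted over the list alone 3 were higher: Chrdl2 (1.70 ± 0.28), Bmper (1.06 ± 0.19) and Grem1 (1.03 ± 0.29, 384 ± 165 FPKM at day 6 against 179 ± 15.5 FPKM in controls). Basement membrane genes were higher (14 tested, median 0.29, camera adjusted p = 0.00897), with Col4a1 and Col4a2 higher adjusted over the list alone. This call was lost without day 6 knockout replicate 1 (adjusted p = 0.144), without the day 4 set control (adjusted p = 0.103) and with controls of the same harvest set (adjusted p = 0.1002). Lipid and adipogenic genes were higher (11 tested, median 0.15, camera adjusted p = 0.0214), with Apod past the threshold and 4 higher adjusted over the list alone. Without day 6 knockout replicate 2 this call was lost (adjusted p = 0.107), as it was with no filter (0.0736), a mean of at least 5 FPKM (0.0862), quantile normalization (0.0721) and TMM factors (0.0676). Interferon-stimulated genes were lower (24 tested, median -0.49, camera adjusted p = 0.00118) with 0 members past the threshold either way. Without day 6 knockout replicate 1 their mean change turned to 0.16 (adjusted p = 0.896). With an estimated correlation none of these 4 calls held: adjusted p = 0.657 with an estimated correlation for the BMP antagonists and the lipid genes, and adjusted p = 0.885 with an estimated correlation for the basement membrane and interferon-stimulated genes. By fry the lipid call held, and adjusted p was 0.237 for the BMP antagonists, 0.936 for basement membrane and 0.939 for interferon-stimulated genes. With the Ddx3y covariate the last 2 were lost too (0.0772 and 0.119), and with a mean of at least 5 FPKM the BMP antagonists (0.0619). Against the day 6 set controls alone, Paneth cell and antimicrobial genes (median 0.88, adjusted p = 0.00154) and blood endothelial markers (0.29, adjusted p = 0.0264) also passed toward higher values. The mean of the Paneth genes was 0.501 in the first of these controls and 1.57 in the second, against 1.63 and 2.05 in the day 6 knockouts. The EGF family ligands had a median of 0.57 at day 6 (camera adjusted p = 0.0655), and 1 of 6, Areg, was higher adjusted over the list alone.

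The day 6 count was 0 without the first day 6 set control, 0 without either day 6 knockout library, 2 without the day 4 set control and 3 without the second day 6 set control. It was also 0 with quantile normalization, and against the 2 day 6 set controls alone 2 genes passed, 1 of them among the 5.

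Of the 120 genes changed at day 4, 113 had the same sign at day 6 (45 of the 47 higher and 68 of the 73 lower), and 114 did when each day was compared with the controls of its own set. All 3 controls entered the choice of these genes, which by itself favours the same sign. In 100 simulations of unchanged groups, the 120 genes with the smallest p at day 4 gave a mean of 84.2% with the same sign (highest 111), and 83.4% (highest 109) with controls of the same set. Genes were simulated independently and without harvest sets, whereas real genes vary together, so the highest simulated counts set no limit for chance. Across the 11735 genes, which are not independent replicates, the log2 changes of the 2 days had r = 0.437 and a covariance of 0.0799. Simulated unchanged groups sharing their controls gave r = 0.403 and a covariance of 0.0341, and with separate controls the observed r was 0.302 and the covariance 0.0600. The genes called at both days were 4: Serpina3m, Apod, Hspb7 and Alpl.

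The direct comparison of day 6 with day 4 asks which responses differ between the days. By limma 0 genes passed, the smallest adjusted p was 0.196, and 1345 genes had an unadjusted p under 0.05 where 587 were expected. The genes with the smallest p that were higher at day 6 were Creb5 (1.42 ± 0.19, log2 change ± SE, adjusted p = 0.240), Nkain4 (1.81 ± 0.27), Tppp3 (2.73 ± 0.41), Hmga1 (1.16 ± 0.17) and Sema3c (1.10 ± 0.17). Those lower were Rgs2 (-1.76 ± 0.21, adjusted p = 0.196), Kcnip3 (-1.27 ± 0.18), Cxcl13 (-2.17 ± 0.31), Gdpd3 (-1.59 ± 0.26) and Alpl (-1.48 ± 0.25). All 10 missed the threshold. Tppp3 was 349 ± 42.5 FPKM (SD, n = 2) at day 6, near the 366 ± 72.7 FPKM (n = 3) of controls.

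As lists, EGF family ligands were lower at day 6 than at day 4 (median -1.19, 0 of 6 positive, camera adjusted p = 0.000192) and fibrillar collagens were higher (median 1.09, 13 of 15 positive, camera adjusted p = 0.000192). With members adjusted over the list alone, 3 ligands were lower (Areg, Epgn and Ereg) and 8 collagens higher (among them Col5a1, Col6a3 and Col5a3). With an estimated correlation both had adjusted p = 0.570 with an estimated correlation, and by fry 0.178 and 0.348. By the column names, the 2 days were separate harvest sets with their own controls. As a difference of within-set differences, which leaves 1 control at day 4, the ligands had a median of -1.57 and the collagens of 0.55. Single genes cannot be read from it where that control is listed at 0, as for Col1a1, Col1a2 and Col3a1. The gene count was 83 without the day 4 set control, 22 without day 4 knockout replicate 1 and 2 without the second day 6 set control.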

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

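Of the tests below, only the count of splits of the libraries was fixed before its result was seen; the splits within harvest sets and the tests of harvest set, paralog reads, sex, sorted cell mixture, carry-over and handling were chosen after the results they address.

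For the 19 genes higher with both days averaged, of 100 drawn from the 105 splits of the 7 libraries into groups of 3, 2 and 2, 4 gave at least 19 genes, the real one included, a share that excludes chance at 0.05 only if all 7 libraries are exchangeable. The 3 larger ones, at 164 to 190, put the day 4 set in the group of 3, which points to a structure of the samples in which harvest set and day 4 knockout are mixed; by group of 3 the count is 2 of 35, and the 18 splits within harvest sets are too few for a share under 0.05 (19 genes, highest other 2). For harvest set, 17 of the 19 passed with controls of the same set. Their median log2 change was 2.13 against 2.14 before, and the median SE 0.233 against 0.212. This fit alone does not decide whether harvest set contributes, because it only reweights the same controls (median move over all genes 0.0348). The 19 genes had also been selected for a small spread among those controls. Against controls of their own set, the 19 genes differed by medians of 2.30 at day 4 (lower quartile 1.75) and 2.06 at day 6 (lower quartile 1.63). The smaller difference of each gene had a median of 1.88 (lower quartile 1.26). An effect shared by the knockouts and controls of a set would leave no such difference. These values argue against harvest set as the whole source of the change in these 19 genes. The selection favours such differences too, and a smaller share of harvest set was not excluded. Reads of Serpina3n given to Serpina3m are argued against by the ratio of the 2 genes, whose lowest knockout value was 2.23 times the highest control value (0.0251 to 0.0436 against 0.00413 to 0.0112). A response of the stroma to loss of Apc in the epithelium may underlie the 19 genes, as a hypothesis found on these same libraries, and neither it nor a change in which cells pass the sort was tested directly. The sort marker Pdgfra was higher in every knockout library (76.5 to 134 FPKM) than in every control (54.3 to 61.3 FPKM). The sort marker Cd81 overlapped (32.4 to 169 FPKM in knockouts, 110 to 149 FPKM in controls).

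For the 120 genes changed at day 4, harvest set was not excluded, because the day 4 set had only 1 control. Over these genes that control lay a median of 0.128 from the day 6 set controls, in the direction of the knockouts. The knockouts lay a median of 1.45 beyond it (lower quartile 1.09). With the control of the same set, the median log2 change thus went from 1.54 to 1.45 and the median SE, now on 1 control, from 0.230 to 0.291. The genes had been selected for a small spread among all controls, which favours these values. Without the day 4 set control 472 genes passed, over which that control lay 0.721 toward the knockout and the knockout a further 0.624 beyond it. These genes were chosen for a large distance between the other libraries, which by itself favours a left-out control in between. The values therefore do not decide whether harvest set carries part of the wider change. Sex of the animals is argued against for the 120 genes. Both day 4 knockouts and 2 controls lacked Y-linked expression, and the knockouts lay medians of 1.63 and 1.45 from those controls (lower quartiles 1.23 and 1.09). Selection of these genes favours such distances and leaves out genes that differ by sex among controls, so this does not extend to other genes. With the Ddx3y covariate 19 of the 120 passed (median change 1.54 before and after, median SE 0.230 and 0.251). By limma 0 genes passed in the 4 libraries without Y-linked expression (1345 at an unadjusted p under 0.05, 2 libraries a side), where the knockouts lay a median of 1.51 from the controls. A larger share of Pdgfra-high cells in the sort cannot be told apart from a change within cells: the telocyte markers had a median log2 change of 0.25 with an upper quartile of 0.883. Their mean was 4.41 in day 4 knockout replicate 2 but 3.40 in replicate 1, near the controls (3.39 to 3.74). The 120 genes moved by 1.49 in replicate 1 and 1.56 in replicate 2. Their call requires such likeness. In replicate 1 they moved without a rise of the telocyte mean, but this rests on 1 library, in which Pdgfra (76.5 FPKM) also lay above all controls. A response to epithelial Apc loss stays open and was not tested directly.

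The EGF family ligands, higher at day 4 with a median of 1.89, were set against RNA from other cells and handling, using marker lists fixed before the data were examined. Epithelial markers had a median change of 0.11 (upper quartile 0.555), handling stress genes of -0.0203 (upper quartile 0.188) and macrophage and dendritic cell markers of -0.35 (upper quartile -0.0971), each below the ligands. Only 5 of the 25 listed epithelial markers were tested. Among the carriers, Epcam was at most 5.70 FPKM and Ptprc at most 8.47 FPKM, where Ereg reached 658 and 1157 FPKM in the day 4 knockouts. Levels of single transcripts do not bound the share of other cells. Macrophage and dendritic cell markers averaged 4.17 in day 4 knockout replicate 1 and 1.43 in replicate 2 (log2 scale), so RNA of such cells was not absent. The ligands averaged 4.59 in replicate 1 and 5.06 in replicate 2, against 3.17 to 3.57 in controls. Their mean was thus highest in the library with the lowest macrophage mean, although replicate 1 had the highest macrophage mean. Induction of these ligands in the stroma by the Apc-deficient epithelium is a hypothesis that no test here decides. A shift toward other Pdgfra-expressing cells was not excluded, since Nrg1 is itself a telocyte marker and Pdgfra lay above all controls in both day 4 knockouts. The telocyte markers averaged 4.41 in replicate 2 but 3.40 in replicate 1, within the range of the controls (3.39 to 3.74).

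The following lists differed between the days by camera on day 6 against day 4, adjusted over 41 lists, and each lost its call with an estimated correlation (adjusted p from 0.570 to 0.874 with an estimated correlation) and by fry (0.178 to 0.748). With controls of the same set, the endothelial markers lost their call with a median near 0 (-0.02, adjusted p = 0.768). There, calls were also lost by lists whose medians kept their sign: collagens (0.55, adjusted p = 0.882), oxidative phosphorylation (-0.16, adjusted p = 0.103), and basement membrane (0.42), interferon-stimulated (-0.42) and macrophage (0.97) genes (adjusted p = 0.0552 for each). EGF family ligands had a median log2 difference of -1.19 (adjusted p = 0.000192) and fibrillar and fibril-associated collagens of 1.09 (adjusted p = 0.000192). Basement membrane genes stood at 0.55 (adjusted p = 0.00137), BMP antagonists at 0.41 (adjusted p = 0.00203; 0.0752 without day 6 knockout replicate 1) and activated fibroblast genes at 0.67 (adjusted p = 0.00203; 0.0560 without day 4 knockout replicate 1). Interferon-stimulated genes stood at -0.41 (adjusted p = 0.00242), and without day 6 knockout replicate 1 their mean turned to 0.24 and without day 4 knockout replicate 1 to 0.05. Paneth cell and antimicrobial genes stood at 0.97 (adjusted p = 0.00484), with a mean per library that reached 2.33 in the day 4 set control and at most 0.652 in the day 4 knockouts; with controls of the same set the median was 2.36 (adjusted p = 1.52e-11). TGF-beta ligands and targets stood at 0.48 (adjusted p = 0.0117; 0.0747 without day 4 knockout replicate 1) and Pi16+ Dpp4+ adventitial fibroblast markers at 0.67 (adjusted p = 0.0123; 0.625 without day 4 knockout replicate 2). Blood endothelial markers stood at -0.57 (adjusted p = 0.0142; 0.106 without day 6 knockout replicate 1 and 0.0516 without day 4 knockout replicate 2). Oxidative phosphorylation genes stood at -0.10 (adjusted p = 0.0253; 0.128 without day 4 knockout replicate 2 and 0.214 without day 6 knockout replicate 2). Telocyte markers stood at -0.50 (adjusted p = 0.0384) and macrophage and dendritic cell markers at 1.07 (adjusted p = 0.0384), and both changed sign without day 4 knockout replicate 2, to means of 0.17 and -0.47, and lost their calls without day 6 knockout replicate 1 (0.115 and 0.522) and without the first (0.0502 for each) or the second (0.0823 and 0.0683) day 6 set control. The macrophage list also lost it without the day 4 set control (0.0779). With the Ddx3y covariate calls were lost by the BMP antagonists (0.0965), TGF-beta (0.478), interferon-stimulated (0.532), macrophage (0.764) and endothelial (0.180) lists.

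Further genes stand out because every day 4 knockout library lay on one side of all controls and every day 6 knockout library on the other. There were 178 such genes where chance gives 112, 7 of them among the 334 genes named under the rule, and the difference between the days missed the threshold for each of the 7. Higher at day 6 than at day 4 were Grem1 by 1.60 (log2, adjusted p = 0.257), Hmga1 by 1.16 (adjusted p = 0.242), Anxa3 by 1.08 (adjusted p = 0.280) and Col5a2 by 0.71 (adjusted p = 0.294). Lower were Gapdh at -1.75 (adjusted p = 0.271), Gdpd3 at -1.59 (adjusted p = 0.246) and Kcnip3 at -1.27 (adjusted p = 0.242). Gapdh was 193 FPKM in the day 4 set control, near the 215 and 277 FPKM of the day 4 knockouts.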

How the results depend on the processing

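Controls of the same harvest set, harvest set as a term, the Ddx3y covariate and zeros set missing were chosen after seeing the data; the other alternatives were planned. Counts of genes are given for day 4, day 6 and both days against wildtype and for day 6 against day 4, where the reported counts are 120, 5, 19 and 0, and lists with both days averaged, where it is 2.

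With no filter on low values the counts at day 4 and with both days averaged were 0 and 0, and 3 at day 6; with a mean of at least 5 FPKM they were 2 at day 6 and 37 with both days averaged, and 1 list passed. A pseudocount of 0.1 gave 2 at day 6. Rescaling to an equal total gave 9 at day 6 and 1 list; quantile normalization gave 0 at day 6, 42 with both days averaged (35 higher and 7 lower, against 19 higher) and 1 list; TMM factors gave 3 at day 6 and 1 list. These scalings moved the median of all genes by less than 0.1. Only the groups compared gave 70 at day 4, 60 between the days and 1 list. A robust prior gave 8 at day 6 and 50 with both days averaged, and no intensity trend 71 at day 4 and 10 at day 6. An adjusted p under 0.1 gave 390, 16 and 124. Controls of the same set leave 1 control for day 4, assumed to vary like the other groups. The median log2 change was then 1.45 for the 120 genes at day 4 and 2.13 for the 19 genes with both days averaged. Genes listed at 0 in that control are distorted there, such as Col1a2, at 9.65 for day 4. Harvest set as a term gave 33 genes and 4 lists with both days averaged, and the Ddx3y covariate 26 at day 4 and 0 at day 6. An estimated correlation left 0 lists, and fry called 1 list, the lipid and adipogenic genes, which is neither of the 2. The cause of these changes was not tested, except where fewer genes or samples were used.

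Leaving out each library in turn gave 2 to 472 genes at day 4, 0 to 6 at day 6, 5 to 77 with both days averaged, 0 to 83 between the days, and 1 to 11 lists; a group left with 1 library is assumed to vary like the others.

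With the replicate number as a replicate block, the counts were 530 at day 4, 0 at day 6, 28 with both days averaged and 53 between the days. The numbers gave no pairing: after group means were removed, libraries sharing a number correlated at -0.0276 (knockouts of both days) and from -0.0693 to 0.293 (controls with knockouts). Control numbers for this block came from the column names, a choice made after seeing the data.

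Direction was kept by every called gene named: 64 results past the threshold gave 1352 checks over 22 alternatives. Of these checks 907 kept the call, 445 lost it and 0 reversed. That 0 reversed was largely fixed in advance and is no test of direction. Results past the threshold had a small spread, and genes named by rank had all knockout libraries beyond all controls. Checks of named results not past the threshold gained a call 208 times. Among results not past it, Derl3, a plasma cell gene, ranged from -2.14 to 2.18 at day 4 when libraries were left out. Means of lists reversed when libraries were left out. Interferon-stimulated genes ranged from -1.18 to 0.16 at day 6 and from -1.07 to 0.24 between the days, turning without day 6 knockout replicate 1 and, between the days, without day 4 knockout replicate 1 (0.05). Between the days and without day 4 knockout replicate 2, telocyte markers turned (range -0.85 to 0.17) and macrophage markers turned (range -0.47 to 2.27). Blood endothelial markers between the days turned to 0.0825 with controls of the same set. Depth is unknown, so it cannot be said which low values it limits; a DESeq2 test was not run.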

Other observations

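Beyond the genes named by the rule, others among the 19 higher with both days averaged were chosen here after their values were seen. Spp1, the secreted phosphoprotein osteopontin, was listed at 0, 0.0464 and 0.0856 FPKM in controls and was 1.64 to 3.41 FPKM in the 4 knockout libraries (adjusted p = 0.0202). Pappa, a protease that releases IGF from its binding proteins, was 2.77 ± 0.0812 FPKM (SD, n = 3) in controls, 13.1 ± 4.27 FPKM (n = 2) at day 4 and 8.99 ± 3.11 FPKM (n = 2) at day 6 (adjusted p = 0.0438). The matrix metalloproteinase Mmp3 and its inhibitor Timp1 were higher in all 4 knockout libraries than in all 3 controls but missed the threshold. Mmp3 was 182 ± 21.1 FPKM in controls and 437 ± 95.6 FPKM (n = 4) in knockouts (log2 change 1.24 ± 0.21, SE, adjusted p = 0.0722). Timp1 was 21.9 ± 3.65 FPKM in controls and 44.9 ± 2.35 FPKM (n = 4) in knockouts (adjusted p = 0.0560).

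Other fixed groups did not pass with both days averaged. The trophocyte markers had a median log2 change of -0.02 (10 tested, camera adjusted p = 0.888), and cell cycle genes 0.09 (18 tested, adjusted p = 0.537). The value was 0.11 for contractile and myofibroblast genes (13 tested, adjusted p = 0.734), -0.26 for Hedgehog targets (10 tested, adjusted p = 0.594) and -0.01 for complement genes (14 tested, adjusted p = 0.658). Chemokine Cxcl10 was 506 to 637 FPKM in controls and 45.2 to 393 FPKM in knockouts (log2 change -2.00 ± 0.57, adjusted p = 0.187), and Saa3, an acute phase protein, was 287 and 142 FPKM at day 4 against 9.38 to 67.7 FPKM in controls.

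Several abundant genes are listed at 0 in single libraries. Dcn was 7745 to 11783 FPKM in 6 libraries and 0 in the day 4 set control. Gsn was 0 in that control and in day 4 knockout replicate 2 and 6350 to 11782 FPKM elsewhere, and Col3a1 was 0 in that control and in day 6 knockout replicate 2 and 1924 to 6687 FPKM elsewhere. In day 6 knockout replicate 2, Xist at 2.17 FPKM stood beside Ddx3y at 9.10 FPKM and Eif2s3y at 8.50 FPKM, while the first day 6 set control and day 6 knockout replicate 1 had Xist at 0.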
